A study of Danio rerio with 56 samples.

How the data were processed

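The samples were single zebrafish cells from the pronephros, the larval kidney, at days 1, 2 and 3 after fertilization. Per the labels, cells of fish carrying green fluorescent reporters for wt1b, a gene of podocytes, and cdh17, a cadherin gene of the pronephric tubule and duct, were sorted by flow cytometry, with 96 wells to a library. RNA of each cell was sequenced with mCEL-Seq2, which counts the 3' ends of polyadenylated RNA and tags each molecule with a random identifier.

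The submitters' processing notes name bcl2fastq 2.17.1.14 and BWA 0.6.2-r126 for demultiplexing and alignment; the genome build is not given in the sources used here, so no positions are reported. The deposited values are estimated counts: expected counts of molecules per gene and cell, computed by the authors from the number of distinct identifiers seen out of 4096, and not normalised. Each library file held 192 columns; a block of 96 columns was taken as the wells of the library when at least 5 of its columns held 1000 transcripts or more. Both blocks met this in the 2 libraries of CDH17_D3, which thus had 192 wells each, against the 96 of the label. The library files listed 27733 gene IDs plus 80 spike-in RNAs, and the reference gave symbols to 19854 of the IDs, which held 82.3% of the transcripts. Of the symbols, 1286 covered more than 1 ID, as for paralogs here, so a symbol such as slc2a1 or tpi1 stands for the single ID tested, given once where the gene is first described. Tables per age with 32662 gene IDs and 2065 columns were also deposited. Of these columns 1744 matched a library well with every gene equal within 1e-06, and 321 were not used. These tables only marked cells the authors kept (matched cells), from 3, 3 and 4 preparations at days 1, 2 and 3.

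A cell was kept with at least 1000 transcripts after leaving out spike-ins and 15 mitochondrial IDs. That left 2460 cells and 9807476 transcripts; 1743 of the kept cells were among the matched columns. No doublet caller was run, since each well received 1 cell. Cells were clustered with scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) on log-normalised values of 2000 variable genes chosen within preparations, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0. Every solute carrier, metabolic, ribosomal, mitochondrial, cell cycle and stress gene of the lists tested below was left out of the clustering. The 25 clusters were named from 18 cell type lists when at least 3 markers of the best list were raised at least 2-fold with detection in at least 10% of cells, and the list either had a mean score of at least 1 or held a gene of the cluster's 10 genes of highest fold, with no other list holding more of them; this naming rule was set after the clusters had been seen. Classes are called proximal-like, distal-like and so on, since nothing but these marker lists names them. The podocyte, proximal, distal and multiciliated classes and any tubule class with its segment open together form the pronephric classes.

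The unit of replication was the preparation: libraries whose titles agree once the trailing library number is removed. This gave 3 preparations at day 1 (12 libraries), 6 at day 2 (22 libraries) and 6 at day 3 (22 libraries). Columns of the tables per age call the cells of ZNI160317_P1 "Split" and those of ZNC151116 and ZNC160317_P1 "Control"; the sample labels do not say what these words or the prefix ZNI mean, and the preparations were pooled by age. Nothing in the labels says whether preparations are separate clutches, so the p values measure spread between preparations, which may be technical. Estimated counts were summed per preparation over all kept cells, the pronephric classes, proximal-like cells and distal-like cells, and rounded to whole numbers. A preparation entered a class only with at least 10 cells of it, and a contrast needed 2 preparations at each age. Distal-like cells met this at days 2 and 3 only.

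Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by age, robust quasi-likelihood fits with all 3 ages in 1 fit, and Benjamini-Hochberg adjustment at 0.05. "Rose" and "fell" refer to genes that passed it. SE is the absolute log2 fold change over the square root of the quasi-likelihood F. Levels are CPM, counts scaled to a total of 1e+06, as mean ± SD over the n preparations. A gene with 0 counts at the earlier age is given as at least N-fold higher, from a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval; both cover counting error only. The difference of the day 3 against day 2 change between proximal-like and distal-like cells was tested with limma 3.58.1 on proximal minus distal log2 CPM within a preparation.

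The 30 gene lists fixed before the data were examined were the solute carriers as a whole family; carriers of glucose, amino acids, bicarbonate and anions, organic ions, monocarboxylates, phosphate, zinc and nucleotide sugars; sodium-proton exchangers, cation-chloride cotransporters and mitochondrial carriers; glycolysis, gluconeogenesis, fatty acid oxidation, the tricarboxylic acid cycle, nuclear-encoded and mitochondria-encoded oxidative phosphorylation, the pentose phosphate pathway and peroxisome; cytosolic ribosomal proteins, cell cycle, motile cilia, receptor-mediated endocytosis, sodium-potassium ATPase, vacuolar proton ATPase, tight junction claudins, nephron transcription factors, glutathione and antioxidant defence, and immediate-early and heat-shock genes. The ribosomal list also took in rps6kb1b, a kinase gene. Lists with at least 3 tested members were tested against the other genes with camera at a preset correlation of 0.01, two-sided, on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move one way, stand beside it. The number of members called is given over all genes and adjusted over the list alone. The 18 marker lists were tested in the same way; cdh17 stands in 3 of them (proximal, distal and tubule with the segment open).

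Class shares were compared between ages by two-sided exact permutation tests on preparations with at least 50 kept cells, adjusted over 48 tests, and depth measures by the same test on all 15 preparations, adjusted over 15. Genes per cell were also counted after thinning each cell to 1000 transcripts. Shares of cells discussed for a single preparation carry 95% Wilson intervals where first given; ranges over preparations do not.

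Before the data were examined, the genes to be named were fixed for each contrast of the pronephric classes: the 6 highest and 6 lowest called genes with a protein name, at least 50 CPM at 1 age and no overlap between the preparations; up to 8 solute carriers and up to 3 members of each of 9 other lists with the smallest adjusted p; and wt1b and cdh17. For proximal-like and distal-like cells and the segment difference, up to 6 solute carriers and 2 members of each other list were named, and for the remaining lists up to 2 members. Genes named outside this rule are said to be chosen after their values were seen. A few genes that the rule names are not reported here.

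Fixed at the same time were the alternatives: leaving out each preparation; 500 or 2000 transcripts per cell; each library as a replicate; broader units that pool ZN_MAX_P1 with ZN_MAX_P2, ZNC160317_P1 with ZNI160317_P1, and the ZNC_Day1 and ZNC_Day3 preparations with their cdh17-titled counterparts; no filter beyond 1 count; RLE scaling; DESeq2 1.42.0; only cells the authors kept; leaving out preparations titled cdh17 or ZNI; all variable genes in the clustering; ComBat before it; Leiden resolution 0.6 and 1.5; a comparison within the ZNC_Day titles; a prior count of 0.5; and, for lists, all kept cells. Leaving out ZNC_Day1_cdh17 and ZNC_D3_080518 was added after the data had been seen.

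The workflow was tested on simulated data with 200 genes changed by known amounts. Of genes changed 4-fold, 16.4% were recovered in all kept cells for day 2 against day 1, 50.7% for day 3 against day 2 and 17.9% for day 3 against day 1; in the pronephric classes these values were 14.9%, 47.8% and 10.4%, and in proximal-like cells 32.8%, 50.7% and 13.4%. In distal-like cells 8.96% were recovered at 4-fold and 56.1% at 16-fold. A raised glycolysis list alone was called in each simulated contrast, but splits of the real data called up to 12. Most calls against day 1 thus needed changes well above 4-fold. Figures used matplotlib 3.10.9.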

Results

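The comparisons ask how expression in the pronephros, of solute carriers and metabolic genes in particular, differs between days 1, 2 and 3. There were 12, 22 and 22 libraries at days 1, 2 and 3, from 3, 6 and 6 preparations. Totals per library without mitochondrial RNA ranged from 76244 to 517802 transcripts at day 1 (median 149278). The range was 33074 to 676471 at day 2 (median 193098) and 1.00 to 517529 at day 3 (median 121090). A single mitochondrial ribosomal RNA (ENSDARG00000080337) held 33.2% of all transcripts. The kept cells numbered 626 at day 1, 984 at day 2 and 850 at day 3. Their median depth per preparation ran from 1885 to 4414 transcripts at day 1, from 1799 to 4018 at day 2 and from 1126 to 3394 at day 3.

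Depth did not differ between ages beyond the spread of preparations. Transcripts per cell averaged 2854 ± 1365 (SD, n = 3) at day 1, 2577 ± 956 (n = 6) at day 2 and 2149 ± 744 (n = 6) at day 3, and genes per cell 1507 ± 507, 1362 ± 279 and 1251 ± 351. After thinning to equal depth, cells held 706 ± 8.76, 692 ± 55.8 and 708 ± 20.9 genes. The 13 mitochondrial messenger RNAs, which encode subunits of oxidative phosphorylation, took 3.22 ± 1.57%, 4.28 ± 2.79% and 5.01 ± 3.54% of transcripts, with two-sided exact permutation p = 0.667 for day 2 against day 1, 0.721 for day 3 against day 2 and 0.50 for day 3 against day 1. The smallest p that 3 against 6 preparations allow is 0.0119, and that of 6 against 6 is 0.00216. No adjusted exact p was below 0.778.

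The sorted cells held tubule, podocyte and many non-renal classes, and the mix differed widely between preparations. Proximal-like cells, named from markers such as hnf4a, pdzk1 and dab2, made up 13 ± 11.6% of kept cells per preparation at day 1 (n = 3), 24.4 ± 19.6% at day 2 (n = 6) and 14.7 ± 7.90% at day 3 (n = 5). Distal-like cells, with the chloride channel gene clcnk and its partner bsnd, made up 5.94 ± 6.52%, 18.8 ± 25.7% (8.63 ± 7.54% without ZNC151116) and 5.42 ± 4.71%. Podocyte-like cells, with the slit diaphragm gene nphs1, made up 1.12 ± 1.95%, 1.3 ± 2.06% and 4.38 ± 6.04%. Multiciliated-like cells numbered 3 at day 1, 12 at day 2 and 11 at day 3. Neural-like cells formed 25.8 ± 28.1% at day 1 (10.8 ± 15.3% without ZNC_Day1_cdh17) against 2.29 ± 3.46% at day 2 and 3.95 ± 5.48% at day 3. Pigment and neural crest cells formed 9.15 ± 6.19%, 0.144 ± 0.223% and 0.270 ± 0.604%. Erythroid cells numbered 25 at day 1 (22 in ZNC_Day1_cdh17, 2 in ZNC_D1CTRL and 1 in ZNC_Day1), against 0 of 984 cells at day 2 and 0 of 850 at day 3, which allow shares of up to 0.305% and 0.353%. Intestine-like cells were 0 of 626 at day 1, which allows up to 0.479%, and made up 2.73 ± 1.06% at day 2 and 14.3 ± 24% at day 3, or 3.60 ± 2.57% without ZNC_Day3_cdh17, where they made up 57.0% (Wilson interval 50.7 to 63.1%). The unnamed clusters held 27.8% of cells at day 1, 33.7% at day 2 and 42.9% at day 3. No share passed the Benjamini-Hochberg adjustment over 48 tests. The smallest two-sided exact permutation p, 0.0119 for endothelium, erythroid, intestine and pigment cells at day 2 against day 1 and 0.0179 for erythroid and pigment cells at day 3 against day 1, equalled the smallest p possible. Their adjusted p was 0.143.

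**Figure D1:**
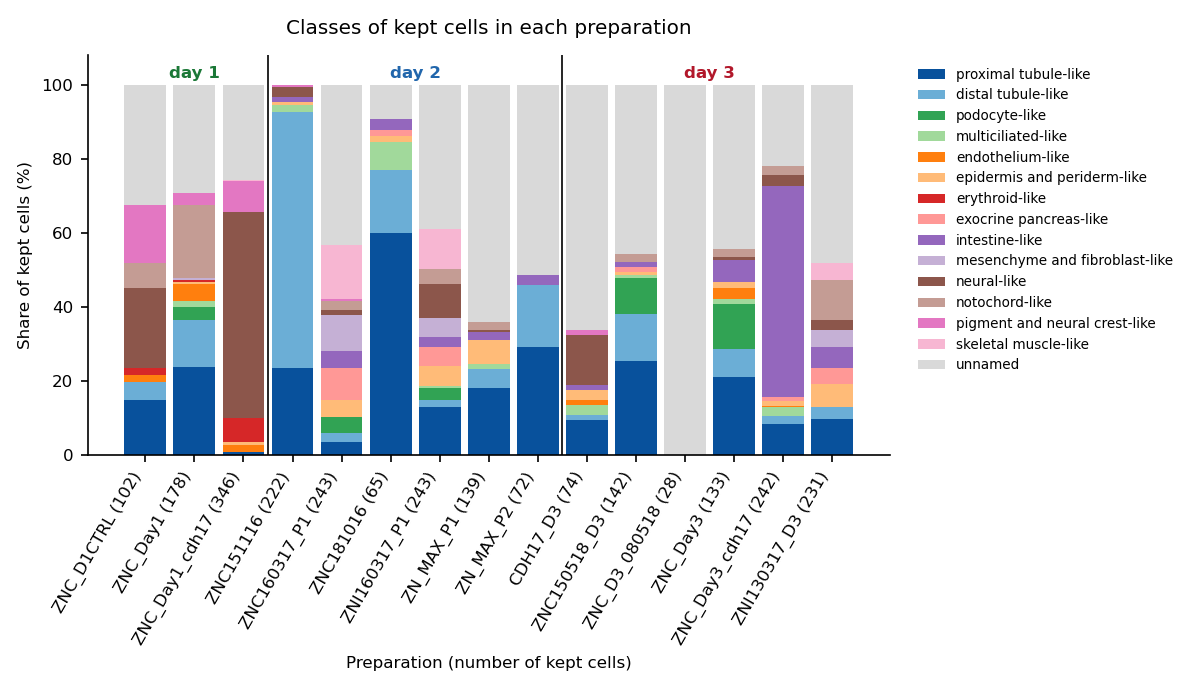
Share of kept cells in each class, stacked in a bar per preparation under its day, with the number of kept cells in brackets. Distal-like cells reach 69.4% in ZNC151116 at day 2 (Wilson interval 63.0 to 75.1%).

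Transcripts of the reporter gene cdh17 (ENSDARG00000005112) separated preparations as much as ages. After thinning, they were seen in 92.3% of the 222 kept cells of ZNC151116 at day 2 (Wilson interval 88.1 to 95.2%) and in 0.867% of the 346 kept cells of ZNC_Day1_cdh17 (0.295 to 2.52%), at median depths of 4018 and 4414 transcripts. ZNC_Day1_cdh17 held 2 cells of the pronephric classes and entered only the comparisons of all kept cells. In that population cdh17 stood at 542 ± 470.1 CPM at day 1 (n = 3), 1643 ± 1624 at day 2 (n = 6) and 439.6 ± 302 at day 3 (n = 6). The last includes ZNC_D3_080518, whose 28 kept cells (median 1126 transcripts) all fell in 1 unnamed cluster. The podocyte transcription factor gene wt1b (ENSDARG00000007990) stood at 30.1 ± 43.7 at day 1 and 65.8 ± 95.2 at day 2. Neither passed the edgeR quasi-likelihood test. The log2 fold changes of cdh17 were 1.60 ± 1.09, -1.88 ± 0.85 and -0.28 ± 1.00 for day 2 against day 1, day 3 against day 2 and day 3 against day 1. Those of wt1b were 1.24 ± 1.45, -0.33 ± 1.12 and 0.91 ± 1.45 (Benjamini-Hochberg adjusted p of 0.621 or more).

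Across the pronephric classes, 5 of the 6 genes called from day 1 to day 2 fell. Starmaker (stm, ENSDARG00000035694), known for its role in otolith mineralisation, fell 19.6-fold, from 1128 ± 510.3 CPM (n = 2) to 53.4 ± 20.1 (n = 6), with adjusted p = 6.89e-05. The 7SK small nuclear RNA (rn7sk, ENSDARG00000081270), whose polyadenylation was not tested, fell 50.6-fold, from 745 ± 142 to 14.7 ± 20.1 (adjusted p = 6.89e-05). The gene neff2 (ENSDARG00000057881) fell 26.4-fold, from 893 ± 673 to 30.5 ± 42.1 (adjusted p = 0.0187). Of 4521 genes tested, edgeR called 1 up and 5 down. The other 3 lack a symbol and were chosen after their values were seen. ENSDARG00000088860 fell by 3.92 and ENSDARG00000003041 by 3.25 on the log2 scale, and ENSDARG00000041884 rose at least 8.14-fold. DESeq2 called 37 up and 24 down, a split of 60.7% up against 16.7%. At unadjusted p under 0.05 edgeR had 284 up and 189 down. Without ZNC_D1CTRL the call of neff2 ended (adjusted p = 0.454), as it did without ZNC181016, and the total fell to 3 and 2 genes without these preparations and to 3 without both ZNI titles. The calls of the 3 unnamed genes also ended without preparations among ZNC151116, ZNC160317_P1, ZNC181016, ZNC_D1CTRL, ZNC_Day1, ZNI160317_P1 and ZN_MAX_P1 (adjusted p up to 0.873). Those of stm and rn7sk stayed past the threshold without any 1 preparation and in the other settings run, while that of neff2 ended with all variable genes in the clustering (0.199). Matched cells (n = 2 and 3) gave 24 up and 51 down.

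None of the 100 solute carriers tested passed between days 1 and 2. At day 2, 56 were higher and 44 lower, with 0 called over all genes and 0 adjusted over the list alone, and camera adjusted p = 0.797. The family median was 0.13 and its mean 0.45 on the log2 scale, although camera ranked it below the other genes. Those with the smallest adjusted p are given here. The facilitative glucose carrier slc2a2 stood at 588 ± 249.7 CPM at day 1 and 153 ± 80.7 at day 2 (log2 fold change -1.95 ± 0.52, adjusted p = 0.206). A subunit of the cystine and dibasic amino acid carrier, slc3a1, stood at 872 ± 588 and 120.2 ± 110.4 (-2.84 ± 0.77, adjusted p = 0.225). In the other direction, the sodium-glucose cotransporter slc5a1 had no count at day 1 and 110.1 ± 101 CPM at day 2, at least 7.77-fold higher. The anion exchanger slc26a6 was at least 3.82-fold higher, and the aromatic amino acid carrier slc16a10 rested on 1 count at day 1 (ratio 35.5, interval 6.30 to 1410). The amino acid carrier slc7a8 stood at 22.2 ± 31.5 and 266 ± 229 CPM, and the monocarboxylate family member slc16a12 at 61.4 ± 55.4 and 272 ± 195. Adjusted over the list alone, slc2a2 passed among 10 glucose carriers, slc3a1 among 23 amino acid carriers, and slc16a10 and slc16a12 among 8 monocarboxylate carriers.

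Several metabolic and housekeeping groups were higher at day 2 than at day 1, by small amounts per gene, in sums whose segment mix also differed. Distal-like cells numbered 28 at day 1 and 195 at day 2, 154 of them in ZNC151116, and proximal-like cells 59 and 176. In proximal-like cells alone oxidative phosphorylation did not pass (camera adjusted p = 0.465). Of 80 nuclear genes of oxidative phosphorylation, 68 were higher at day 2, with a median log2 difference of 0.46 (camera adjusted p = 0.00215). The ATP synthase gene atp5mc3b stood at 1209 ± 112.3 CPM and 3197 ± 1302 (log2 1.41 ± 0.44, edgeR adjusted p = 0.277). The genes cox6a1 and cox7a1 of cytochrome oxidase were also higher, the latter at least 9.31-fold. Ribosomal protein genes were higher in 73 of 76 cases (median 0.66, adjusted p = 1.60e-08), and genes of glutathione and antioxidant defence in 15 of 17 (median 1.06, adjusted p = 0.00215). Of the antioxidant genes, peroxiredoxin prdx1 (ENSDARG00000025350) stood at 84.7 ± 6.01 and 431 ± 105 CPM and gstt1a at 61.4 ± 55.4 and 326 ± 111.7. Motile cilia genes were lower in 30 of 35 (median -0.64, adjusted p = 0.00215), among them hydin (211 ± 14.9 and 53.1 ± 48.3 CPM), capsl and cfap57. With an estimated correlation all 4 lists had adjusted p = 0.798, and none passed. The smallest adjusted p of fry was 0.702. None of the members of these 4 lists was called, over all genes or adjusted over the list alone. Without ZNC_D1CTRL 10 of the 25 lists passed, without ZNC_Day1 1 and without ZNI160317_P1 7, as without both ZNI titles.

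Glycolysis and the remaining lists did not pass between days 1 and 2. Glycolytic genes were higher in 11 of 13 cases (camera adjusted p = 0.0984). Here gapdh (ENSDARG00000043457) stood at 105 ± 22.5 and 443 ± 223 CPM (log2 2.13 ± 0.66, adjusted p = 0.277), eno3 at 412 ± 214 and 1119.7 ± 449 and ldhb at 685 ± 29.9 and 1713 ± 921. Gluconeogenesis split evenly over 4 genes (adjusted p = 0.990), with g6pc1 (ENSDARG00000013721) at a ratio of 7.86 (2.11 to 66.0) and fbp1b at -1.06 ± 0.65. Fatty acid oxidation was higher in 14 of 18 (adjusted p = 0.115), led by cpt1ab at 34.0 ± 8.79 and 136 ± 80.8 CPM. The tricarboxylic acid cycle was higher in 17 of 20 (adjusted p = 0.172). For endocytosis, cathepsin D (ctsd) stood at 97.6 ± 4.29 and 332 ± 138 CPM (list adjusted p = 0.121). For the cell cycle the replication clamp pcna stood at 43.4 ± 33.0 and 394 ± 268 (0.141), and it passed adjusted over the list alone. For immediate-early and heat-shock genes atf3 was at -2.26 ± 0.96 and hsp70l at 6.87 ± 3.42 (0.141). Nephron transcription factors such as sim1 (-1.92 ± 0.85), gata3 (1.25 ± 1.18) and pax8 (0.51 ± 0.59) gave 0.585 and claudins with cldn3c (-1.22 ± 0.44) 0.0646. The vacuolar proton ATPase with atp6v1a (2.42 ± 0.72, past the threshold adjusted over the list alone) gave 0.473. The peroxisome list gave 0.417, with hao1 past the threshold adjusted over the list alone (2.81 ± 0.89), and the sodium-potassium ATPase 0.614, with atp1b2 at -1.09 ± 0.57. The 8 carrier lists left gave between 0.20 and 0.824. Median and test, or median and mean, differed in sign for 4 and 7 of the 25 lists. Cation-chloride cotransporters (slc12a3 at 0.42 ± 0.93), nucleotide sugar carriers (slc35d2 at -1.11 ± 0.52), zinc carriers (slc30a1 at 1.05 ± 0.63) and the pentose phosphate pathway (pgd at -0.07 ± 0.73) had too few tested members for a set test. None of the 9 marker lists tested passed (smallest adjusted p = 0.204). Neither reporter gene passed, with wt1b at 0.92 ± 1.97 and cdh17 0.27 ± 0.43 on the log2 scale (2797 ± 769 and 3371 ± 1228 CPM).

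Between days 2 and 3, an anion exchanger and a glucose carrier were lower on average at day 3 in the pronephric classes, without passing. The anion exchanger slc4a2 (ENSDARG00000028173) stood at 3795 ± 1461 CPM at day 2 (n = 6) and 954 ± 459 at day 3 (n = 5), a log2 fold change of -1.97 ± 0.38 (edgeR adjusted p = 0.102). The glucose carrier slc2a1 (ENSDARG00000001437) stood at 1246 ± 1332 and 95 ± 79.1 (-3.71 ± 0.95, adjusted p = 0.287), with ZNC181016 at 3847 CPM and the other day 2 preparations at 225 to 1148. Without ZNC181016 the log2 fold change was -2.95. Some other carriers were higher at day 3, without passing. The organic anion carrier slc22a8 stood at 39.2 ± 22.3 and 143 ± 66.6 (2.18 ± 0.54, adjusted p = 0.233) and the organic cation exporter slc47a2.1 at 289 ± 136 and 738 ± 383. Of the monocarboxylate family, slc16a9 stood at 26.6 ± 42.7 and 207 ± 184, slc16a6 at 33.8 ± 37.8 and 124 ± 90.8, and slc16a1 (ENSDARG00000016963) at 122 ± 39.6 and 289 ± 143. As a list, organic ion carriers were higher in 7 of 8 cases (median 1.00, camera adjusted p = 0.00125) and monocarboxylate carriers in 5 of 8 (median 0.80, adjusted p = 0.0331). The adjusted p was 0.246 for both with an estimated correlation and 0.199 by fry. Adjusted over the list alone, slc22a8 and slc47a2.1 passed among organic ion carriers and slc16a9, slc16a6 and 2 genes named slc16a1 among monocarboxylate carriers. Of all 100 solute carriers 52 were higher and 48 lower. None was called over all genes, with slc22a8 up and slc4a2 down adjusted over the list alone, and camera adjusted p = 0.286.

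Genes of mitochondrial respiration and of ribosomes were lower at day 3 than at day 2 as groups, although 54 of 100 splits of the same preparations called at least as many lists. Oxidative phosphorylation was lower in 75 of 80 genes (median -0.51, camera adjusted p = 3.91e-09; adjusted p = 0.949 with an estimated correlation), for example atp5po at 1261 ± 467 and 644 ± 441 CPM (-0.94 ± 0.39) and uqcrh at 1078 ± 425 and 631 ± 254. The tricarboxylic acid cycle was lower in 19 of 20 (median -0.51, adjusted p = 0.000796), and ribosomal proteins in 73 of 76 (median -0.51, adjusted p = 1.68e-09), for example rps20 at 2649 ± 537 and 1509 ± 201. The latter 2 also had adjusted p = 0.949 with an estimated correlation, and 0 members of the 3 lists were called, over all genes or adjusted over the list alone. The other lists did not pass. Glycolysis (0.945) had gapdh at 443 ± 223 and 875 ± 335 CPM (0.96 ± 0.40, adjusted p = 0.498) and ldhb at -0.73 ± 0.42. Gluconeogenesis (0.945) had pck2 at 1.24 ± 0.65, and fatty acid oxidation (0.945) had etfdh at 0.94 ± 0.47 and acsl1 at -0.77 ± 0.41. The transcriptional coactivator gene ppargc1a, of the nephron transcription factors (0.945), stood at 746 ± 459 and 381 ± 147 CPM. Immediate-early genes (0.825) had egr1 at 45.0 ± 30.7 and 236 ± 261, and motile cilia (0.148) dnah7 at 1.88 ± 0.78 and enkur at -1.05 ± 0.44. The cell cycle (0.945) had pcna at -0.93 ± 0.53, and endocytosis (0.945) dab2 at 1.04 ± 0.58. Phosphate carriers were higher in 5 of 5 (0.0580), with slc34a1 and slc20a1 past the threshold adjusted over the list alone. The sodium-potassium ATPase was lower in 7 of 9 (0.0652), with 1 member up and 3 down adjusted over the list alone, atp1b2 at 1.31 ± 0.45 among them. The 9 lists left gave between 0.576 and 0.945. The carrier slc2a1 passed among glucose carriers, and slc4a2 and slc26a6 among anion exchangers, adjusted over the list alone. Cation-chloride cotransporters (slc12a3 at -1.50 ± 0.70), nucleotide sugar carriers (slc35b2 at 1.22 ± 0.51), zinc carriers (slc30a1 at -0.42 ± 0.42) and the pentose phosphate pathway (pgd at 0.37 ± 0.53) had no set test. Distal-like cells made up 69.4% of the kept cells of ZNC151116 at day 2, so the mix of segments moved with the preparations compared here.

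Only 1 of 4521 genes was called between days 2 and 3 in the pronephric classes: ENSDARG00000003041, without a symbol and named after its value was seen, rose from 49.1 ± 17.5 to 534 ± 328 CPM (adjusted p = 0.0156). DESeq2 called 11 up and 7 down, and 214 and 172 genes had an unadjusted p under 0.05 in edgeR. That call ended without ZNC150518_D3, ZNC181016, ZNC_Day3, ZNI160317_P1 or ZN_MAX_P1 (adjusted p up to 0.10), without both ZNI titles, with broader preparation units and with a minimum of 2000 transcripts (up to 0.170). Matched cells (n = 3 and 4) gave 64 genes up and 60 down. The total was 3 genes without ZNC151116 or ZNC160317_P1 and 8 without ZN_MAX_P2. The lists that passed numbered 8 without ZNC181016 or ZNI160317_P1. The reporter genes did not pass: cdh17 stood at 3371 ± 1228 and 1868 ± 846 CPM (-0.85 ± 0.32, adjusted p = 0.436) and wt1b at -0.80 ± 1.45.

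From day 1 to day 3 slc2a1 and the high-mobility group gene hmga2 fell in the pronephric classes. The glucose carrier slc2a1 fell 82.9-fold, from 7946 ± 6636 CPM (n = 2) to 95 ± 79.1 (n = 5), with a log2 fold change of -6.37 ± 1.1 and adjusted p = 0.0423. The chromatin protein gene hmga2 (ENSDARG00000069912), known from embryonic tissue, fell 8.21-fold, from 4374 ± 1640.0 to 549 ± 277 (adjusted p = 0.00822). Also lower were stm (29.8-fold, adjusted p = 6.51e-05), neff2 (80.4-fold, adjusted p = 0.00884), rn7sk (9.05-fold, adjusted p = 0.0256), mdp1 (ENSDARG00000088040, 7.99-fold, adjusted p = 0.0256) and the keratin krt18a.1, named after its value was seen (6.20-fold, adjusted p = 0.0256). In all, 1 gene was called up and 9 down. The remaining 3 lack symbols (ENSDARG00000088860 and ENSDARG00000062581 down, ENSDARG00000004909 at least 8.69-fold up, chosen after their values were seen). DESeq2 called 24 up and 26 down, 48% up against 10%. In edgeR 205 and 169 genes had an unadjusted p under 0.05. The slc2a1 call ended without any 1 preparation except ZNC150518_D3 (adjusted p up to 0.494, without ZNC_D1CTRL; 1.89e-10 to 0.264 over the other settings). Those of neff2 and hmga2 ended without ZNC_D1CTRL (0.172 and 0.221). The calls of rn7sk, mdp1, krt18a.1, ENSDARG00000062581 and ENSDARG00000004909 each ended without ZNC_D1CTRL, ZNC_Day1 or ZNC_Day3_cdh17, most also without ZNI130317_D3, CDH17_D3, ZNC150518_D3 or ZNC_Day3. With all variable genes in the clustering stm and ENSDARG00000088860 alone were called. The total was 2 without ZNC_D1CTRL, 4 without ZNC_Day1 or ZNC_Day3_cdh17, 5 without ZNI130317_D3 and 6 without both ZNI titles.

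Among the 100 solute carriers, 62 were higher and 38 lower at day 3 than at day 1. In edgeR 0 were called up and 1 down over all genes and 6 up and 6 down adjusted over the list alone (camera adjusted p = 0.437). Besides slc2a1, slc4a2 stood at 3873 ± 1182 and 954 ± 459 CPM (-2.0 ± 0.46, adjusted p = 0.0841) and slc3a1 at 872 ± 588 and 65.1 (-3.63 ± 0.85, adjusted p = 0.0917). The glycine carrier slc6a9 stood at 603 ± 286 and 141 ± 35.6, and slc2a2 at 588 ± 249.7 and 144.6 ± 58.3. The anion exchanger slc26a6 was at least 16.9-fold higher at day 3 (adjusted p = 0.0917), slc16a10 had a ratio of 22.3 (3.81 to 898), and slc7a8 stood at 22.2 ± 31.5 and 324 ± 201. The 1 list that passed was glutathione and antioxidant defence, higher in 13 of 17 genes (median 1.32, camera adjusted p = 0.0325). Its adjusted p was 0.773 with an estimated correlation. Here gstt1a stood at 61.4 ± 55.4 and 384 ± 341 CPM and superoxide dismutase sod1 at 49.7 ± 15.2 and 162 ± 84.3. Without ZNC150518_D3 or ZNI130317_D3 no list passed. Without ZNC_D1CTRL 10 did, without ZNC_Day1 or ZNC_Day3_cdh17 3, and without CDH17_D3 or ZNC_Day3 2. Among glycolytic genes gapdh stood at 105 ± 22.5 and 875 ± 335 CPM (3.09 ± 0.70, adjusted p = 0.0826, past the threshold adjusted over the list alone) and pgam1a at 1.48 ± 0.51, while tpi1 (ENSDARG00000040988) was at -1.19 ± 0.50 (list adjusted p = 0.149). Oxidative phosphorylation was split, 37 higher and 43 lower (median -0.01, mean 0.17, adjusted p = 0.396), as was the tricarboxylic acid cycle (12 and 8, adjusted p = 0.378). The values for the other lists were 0.761 for gluconeogenesis, 0.167 for fatty acid oxidation (cpt1ab at 2.07 ± 0.72), and 0.259 for ribosomal proteins. They were 0.196 for the cell cycle (pcna at 2.03 ± 0.86) and for endocytosis (ctsd and ctsz past the threshold adjusted over the list alone, at 2.24 ± 0.63 and 2.88 ± 0.88). They were 0.0949 for motile cilia (enkur at -1.69 ± 0.55), for organic ion carriers (slc47a4 at 3.52 ± 1.09) and for the sodium-potassium ATPase. Nephron transcription factors gave 0.47 (mafb at 2.48 ± 1.24), with 0.304 for immediate-early and heat-shock genes (klf6 at -1.81 ± 0.69), and between 0.167 and 0.925 for the 10 lists left. Median and test differed in sign for 4 lists. The reporter genes gave 0.11 ± 1.97 for wt1b and -0.57 ± 0.42 for cdh17.

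**Figure D2:**
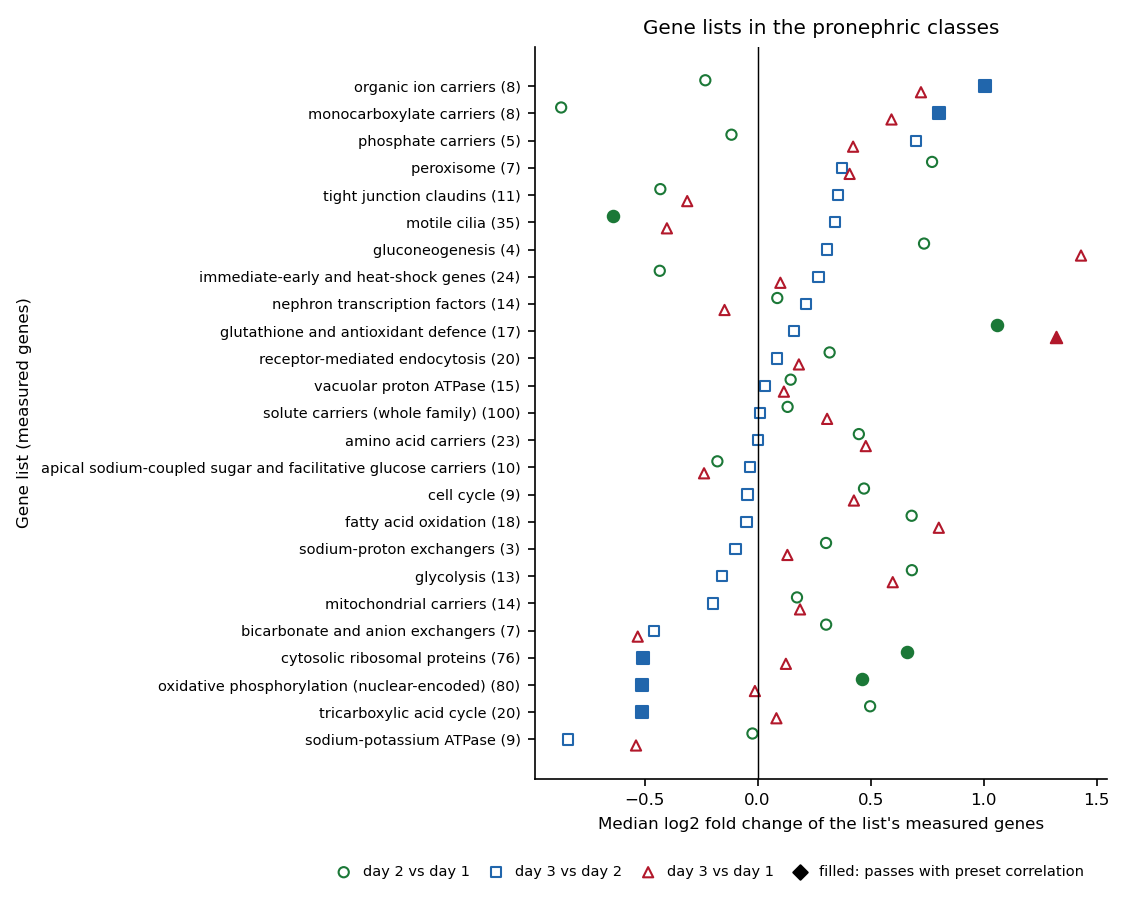
Median log2 fold change of each gene list in the pronephric classes for the 3 age contrasts, with filled points where camera passed at the preset correlation. Oxidative phosphorylation sits at 0.46 for day 2 against day 1 and at -0.51 for day 3 against day 2.

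Within proximal-like cells, the genes called from day 1 to day 2 (n = 2 and 5) again included losses of stm (15-fold, adjusted p = 0.000339) and rn7sk (50.1-fold, adjusted p = 0.000712), with hmga2 falling from 5338 ± 1231 to 1621 ± 120.1 CPM (adjusted p = 0.0263). Selenoprotein P (selenop, ENSDARG00000093549), a secreted selenium carrier, rose from 3301 ± 615 to 14025 ± 6468 CPM (adjusted p = 0.0495), and adenosylhomocysteinase (ahcy) from 216 ± 35.9 to 1191 ± 275 (adjusted p = 0.0498). These genes were chosen after their values were seen. Solute carriers did not pass, with 40 of 67 higher and 0 called, over all genes or adjusted over the list alone (camera adjusted p = 0.976). The amino acid carrier slc3a1 stood at 1299 ± 519 and 216 ± 152 CPM (-2.61 ± 0.64, adjusted p = 0.0721), slc2a2 at 905 ± 165 and 277 ± 96.3 and slc16a12 at 91.1 ± 61.2 and 459 ± 245. The cotransporter slc5a1 was at least 9.95-fold and slc26a6 at least 4.89-fold higher, and slc3a2a had a ratio of 7.72 (2.05 to 65.2). Glycolysis was higher in 7 of 9 genes (median 1.0, camera adjusted p = 0.0108; adjusted p = 0.664 with an estimated correlation). In this list eno3 stood at 402 ± 78.1 and 1526 ± 553 CPM (1.94 ± 0.45, adjusted p = 0.0548) and gapdh at 113 ± 8.44 and 680.3 ± 365 (2.56 ± 0.66, adjusted p = 0.0780), both past the threshold adjusted over the list alone. Ribosomal proteins (72 of 74 higher, adjusted p = 4.47e-06) and antioxidant genes (13 of 15 higher, adjusted p = 0.0304) also passed upward, with adjusted p = 0.831 and 0.806 with an estimated correlation. Motile cilia (6 of 7 lower, adjusted p = 0.0102, with cfap57 and hydin), claudins (5 of 5 lower, adjusted p = 0.0102, with cldn3c and cldn3d) and immediate-early genes (12 of 20 lower, adjusted p = 0.0304, with atf3 at -3.01 ± 0.86) passed downward. With an estimated correlation their adjusted p was 0.664 for cilia and claudins and 0.831 for immediate-early genes. Oxidative phosphorylation did not pass (0.465; atp5mc3b at 1129 ± 228 and 3012 ± 821 CPM), nor did gluconeogenesis (0.733; g6pc1 ratio 21.3, 3.71 to 849) or fatty acid oxidation (0.245; acaa2 at 1.81 ± 0.69). The cell cycle (0.403; pcna ratio 18.8), endocytosis (0.199; ctsla at 1.87 ± 0.60) and nephron transcription factors (0.821; mafb at 1.28 ± 0.54) did not pass either. The reporter gene cdh17 stood at 3237 ± 591 and 3454 ± 877 CPM. Of 2712 genes edgeR called 5 up and 12 down, 29.4% up, and with RLE scaling 13 up and 17 down, 43.3% up. DESeq2 called 42 and 37. The calls of hmga2, selenop and ahcy ended without ZNC151116, ZNC181016, ZNC_D1CTRL, ZNC_Day1 or ZN_MAX_P1 (adjusted p up to 0.424). That of hmga2 also ended with no filter on low counts (0.0571), and those of selenop and ahcy with broader preparation units or without the preparations titled cdh17 (up to 0.0783). Matched cells (n = 2 and 2) gave 29 up and 67 down. The total was 5 without ZNC151116, ZNC_D1CTRL or ZN_MAX_P1, 4 without ZNC181016 or ZNC_Day1, 38 without ZNI160317_P1, 36 without both ZNI titles and 30 without ZN_MAX_P2.

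In proximal-like cells 1 carrier fell and another rose between days 2 and 3 (n = 5 and 4). The anion exchanger slc4a2 fell 4.09-fold, from 6733 ± 490 CPM to 1634 ± 735 (log2 -2.03 ± 0.29, adjusted p = 0.00263), and the organic anion carrier slc22a8 (ENSDARG00000055523) rose 8.71-fold, from 33.9 ± 25.3 to 267 ± 102 (3.12 ± 0.55, adjusted p = 0.0184). The thyroid hormone deiodinase gene dio3b (ENSDARG00000095767), chosen after its value was seen, fell 9.21-fold, from 2057 ± 910.3 to 215 ± 75.7 (adjusted p = 0.00193). The other 6 called genes, also chosen after their values were seen, were ttc19, ENSDARG00000088860 and ENSDARG00000015512 down and tcim, stc1 and ENSDARG00000003041 up. The hormone gene stc1 (ENSDARG00000058476) went from 27.6 ± 34.1 to 665 ± 699 CPM and was also the leading gene of an unnamed cluster found mostly in ZNC_Day3_cdh17. Of 67 solute carriers 1 was called up and 1 down, 8 and 5 adjusted over the list alone, with 36 higher (camera adjusted p = 0.123). Here slc2a1 stood at 2195 ± 1861 and 144 ± 143 (-3.87 ± 0.85, adjusted p = 0.105; -3.19 without ZNC181016, which stood at 5454 CPM) and slc6a9 at 608 ± 121 and 231 ± 64.5. The amino acid carrier slc38a5b stood at 345 ± 128 and 118.5 ± 39.2, and slc16a1 (ENSDARG00000068572) at 311 ± 102 and 842 ± 304. Organic ion carriers were higher in 7 of 7 (camera adjusted p = 0.000354) and monocarboxylate carriers in 5 of 6 (0.00709), each with adjusted p = 0.161 with an estimated correlation and 0.0520 by fry. Ribosomal proteins were lower in 72 of 74 (5.95e-06) and immediate-early genes higher in 12 of 20 (0.00697; egr1 at 36.9 ± 32.5 and 277 ± 186 CPM, hsp90aa1 at 2.44 ± 0.96). Both had adjusted p = 0.844 with an estimated correlation. Among lists that did not pass, glycolysis gave 0.924 (gapdh at 1.01 ± 0.41), gluconeogenesis 0.407 (pck2 at 1.1 ± 0.59) and fatty acid oxidation 0.802 (acsl1 at -1.73 ± 0.66). Oxidative phosphorylation gave 0.508 (ndufa4b at 1.90 ± 0.58, atp5mc3b at -0.62 ± 0.26), the cell cycle 0.108 (top2a at 3.02 ± 0.98) and motile cilia 0.49 (enkur at -1.62 ± 0.55). Endocytosis gave 0.508 (ctsd at 1.06 ± 0.39) and nephron transcription factors 0.590 (mafb at 1.19 ± 0.36), and cdh17 was at -0.73 ± 0.25 (adjusted p = 0.240). The slc4a2 and dio3b calls stayed without any 1 preparation. With matched cells only (n = 2 and 3) they ended at -2.16 (adjusted p = 0.0674) and -2.50 (0.0580), and 1 gene was called. The slc22a8 gene lost its call without ZNC150518_D3, ZNC181016, ZNC_Day3, ZNI160317_P1 or ZN_MAX_P1 (adjusted p up to 0.103), without both ZNI titles and with a minimum of 2000 transcripts (up to 0.222). So did ttc19, tcim, stc1, ENSDARG00000015512 and ENSDARG00000003041 without ZNC150518_D3 or ZNC181016 (up to 0.188), the first 4 also without others among ZNC151116, ZNC_Day3, ZNC_Day3_cdh17, ZNI160317_P1, ZN_MAX_P1 and ZN_MAX_P2. In all 4 were called up and 5 down, and DESeq2 called 15 and 24. The total was 3 without ZNC150518_D3 or ZNC181016, 5 without ZNC_Day3_cdh17, 16 without ZNI130317_D3 and 18 without both ZNI titles.

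Over the whole interval, day 1 to day 3, 6 solute carriers fell and 3 rose in proximal-like cells (n = 2 and 4). The glucose carrier slc2a1 fell 78.4-fold, from 11768 ± 7149.8 to 144 ± 143 CPM (log2 -6.29 ± 0.98, adjusted p = 0.00777). Lower too were slc4a2, from 6190.0 ± 12.4 to 1634 ± 735 (-1.91 ± 0.34, adjusted p = 0.00950), and the bicarbonate cotransporter slc4a4 (ENSDARG00000013730), from 9539 ± 2207 to 3182 ± 1377 (-1.58 ± 0.38, adjusted p = 0.0465). So were slc3a1 (ENSDARG00000017165), from 1299 ± 519 to 117 ± 99.1 (-3.54 ± 0.72, adjusted p = 0.0231), and slc6a9 (ENSDARG00000018534), from 944 ± 186 to 231 ± 64.5 (-2.0 ± 0.43, adjusted p = 0.0298). The anion exchanger slc26a6 (ENSDARG00000097292) rose at least 16.6-fold, from no count to 369 ± 226 CPM (adjusted p = 0.0231). Of 67 solute carriers 3 were called up and 6 down, 6 and 7 adjusted over the list alone, with 40 higher and 27 lower (camera adjusted p = 0.202). The other 3, chosen after their values were seen, were slc38a5b (496 ± 92.9 to 118.5 ± 39.2 CPM), the inositol carrier slc5a11 (44.8 ± 12.7 to 253 ± 23.4) and the amino acid carrier subunit slc3a2a (ratio 13.7, 3.62 to 115.7). Without ZNC_D1CTRL the calls of slc2a1 (adjusted p = 0.107), slc4a2, slc3a1 and slc26a6 ended. So did those of slc4a2 (0.125), slc3a1 and slc26a6 (0.250) without ZNC_Day1, of slc3a1 and slc26a6 without ZNC150518_D3 and of slc3a1 without ZNC_Day3. The genes slc6a9, slc4a4, slc38a5b, slc5a11 and slc3a2a lost theirs without any 1 of the 6 preparations (up to 0.471). These and slc26a6 also lost theirs without both ZNI titles, and slc4a2 with matched cells only (0.0638). Over the other settings slc2a1 stayed called except with no filter on low counts (0.0545) and with each library as a replicate (0.0878).

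**Figure D3:**
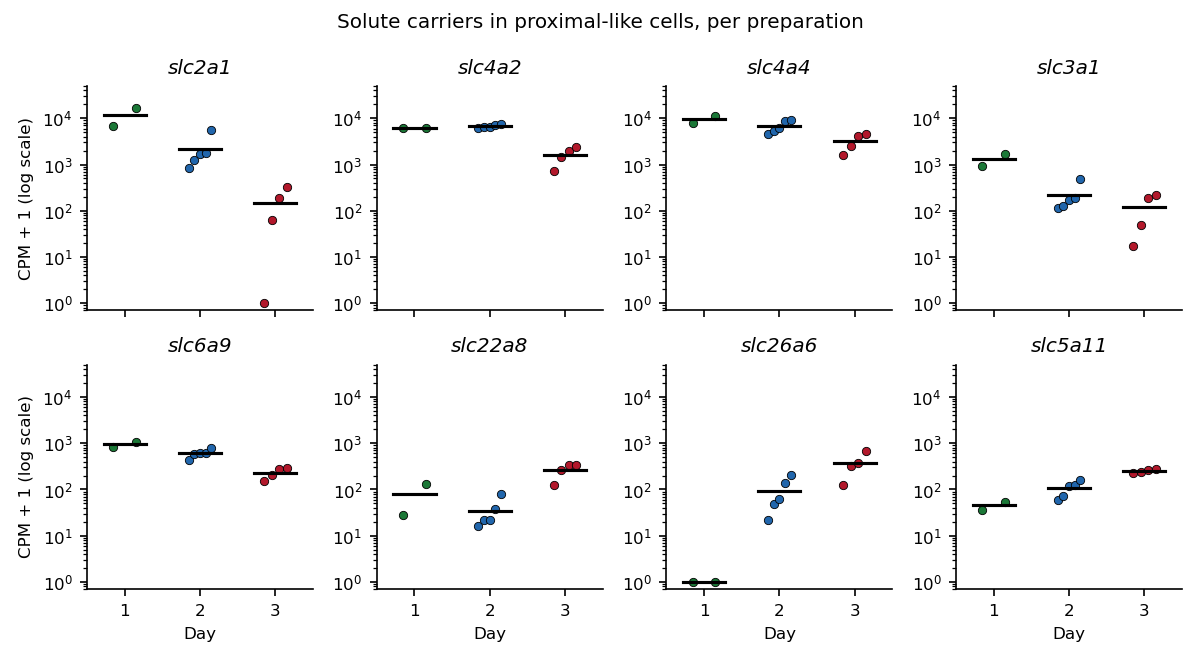
CPM + 1 on a log axis of 8 solute carriers in proximal-like cells, with a point per preparation coloured by day and bars at the mean CPM of each age. The means of slc2a1 go from 11768 CPM at day 1 to 2195 at day 2 and 144 at day 3, and those of slc26a6 from 0 to 369.

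In the same proximal-like cells the genes gapdh, ctsd, ctsz and mafb rose between days 1 and 3. The glycolytic enzyme gene gapdh rose 11.9-fold, from 113 ± 8.44 to 1376 ± 328 CPM (3.57 ± 0.69, adjusted p = 0.0155). Glycolysis was higher in 7 of 9 genes (median 0.86, camera adjusted p = 0.0254), with eno3 at 402 ± 78.1 and 1126 ± 262 CPM (adjusted p = 0.0965) and 3 up and 1 down, tpi1, adjusted over the list alone. The list had adjusted p = 0.335 with an estimated correlation. The lysosomal proteases ctsd (113 ± 8.44 to 705 ± 290.1 CPM, adjusted p = 0.0394) and ctsz (ratio 11.4, 3.73 to 56.4, adjusted p = 0.0353) rose, as did the transcription factor gene mafb (82.1 ± 2.11 to 464 ± 139 CPM, adjusted p = 0.0353). Antioxidant genes were higher in 13 of 15 (median 0.90, adjusted p = 0.00666), with 2 called and 5 adjusted over the list alone, among them sod2 and gstt1a, and adjusted p = 0.335 with an estimated correlation. Organic ion carriers were higher in 4 of 7 (median 1.60, adjusted p = 0.0254, with slc13a1 and slc47a4 adjusted over the list alone) and cell cycle genes in 6 of 7 (median 1.42, adjusted p = 0.0254), with pcna at a ratio of 16.3 (4.35 to 138). Both had adjusted p = 0.335 with an estimated correlation. Motile cilia genes were lower in 7 of 7 (median -1.79, adjusted p = 0.00255; enkur at 312 ± 52.8 and 56 ± 31.9 CPM) and claudins in 4 of 5 (median -1.49, adjusted p = 0.0255). These 2 lists also had adjusted p = 0.335 with an estimated correlation, and fry gave 0.0750 at the lowest over the 6 lists. Gluconeogenesis (0.246; g6pc1 ratio 28.8, 4.98 to 1157), fatty acid oxidation (0.127; acsl1 at 222 ± 27.5 and 32.7 ± 15.4 CPM) and oxidative phosphorylation (0.742; ndufa4b at 2.55 ± 0.91) did not pass as lists. Nor did endocytosis (0.0722), nephron transcription factors (0.970; ppargc1a at -1.07 ± 0.54) or immediate-early genes (0.742; klf6 at -1.66 ± 0.80), and cdh17 was at -0.63 ± 0.32. Of 2712 genes 24 were called up and 25 down (DESeq2 57 and 55). Among those chosen after their values were seen, hmga2 fell 8.06-fold (adjusted p = 0.000200), ptmaa 17.4-fold (0.00144) and the acetyltransferase gene nat8 6.56-fold (0.00156), and selenop rose 5.46-fold to 18012 ± 1817 CPM (0.0153). The calls of gapdh and selenop ended without ZNC_D1CTRL or ZNC_Day1 (up to 0.235), that of nat8 without ZNC_D1CTRL (0.0671). Those of ctsd, ctsz and mafb ended without any 1 preparation except ZNC_Day3_cdh17 (up to 0.387), without both ZNI titles and with a minimum of 500 transcripts (up to 0.123). The total was 17 without ZNC150518_D3, 6 without ZNC_D1CTRL, 10 without ZNC_Day1, 23 without ZNC_Day3, 30 without ZNC_Day3_cdh17, 18 without ZNI130317_D3 and 23 without both ZNI titles.

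Distal-like cells could be compared only between days 2 (n = 3) and 3 (n = 2), and there 4 of the 13 tested immediate-early and heat-shock genes rose. The chaperone gene hsp90aa1 (ENSDARG00000024746) rose from 11.5 ± 19.9 to 2150.5 ± 624 CPM (log2 6.39 ± 1.03, adjusted p = 0.00530). The gene atf3 (ENSDARG00000007823) rose by a ratio of 302 (50.8 to 12247, adjusted p = 0.0134). The AP-1 genes fosl1 (at least 117-fold, adjusted p = 0.0134) and fos (12.3 to 1118 ± 1011 CPM, adjusted p = 0.0187) and the kinase gene mknk2 (43.0 to 1157 CPM, adjusted p = 0.0386), chosen after their values were seen, completed the 5 genes called, all up, of 1421 tested. The immediate-early and heat-shock list was higher in 12 of 13 genes (median 3.18, camera adjusted p = 7.14e-09), with 4 called and 7 adjusted over the list alone. Its adjusted p was 0.881 with an estimated correlation and 0.222 by fry. Oxidative phosphorylation was lower in 73 of 76 genes (median -0.83, adjusted p = 1.91e-07), for example atp5f1c at 2602 and 714 CPM and uqcrc2a at -2.38 on the log2 scale. The tricarboxylic acid cycle was lower in 17 of 17 (median -0.89, 0.0139) and ribosomal proteins in 69 of 72 (0.00596), with adjusted p = 0.907 for each with an estimated correlation. None of the 32 solute carriers was called, over all genes or adjusted over the list alone, with 14 higher and 18 lower (camera adjusted p = 0.709). The exporter slc47a2.1 stood at 322 ± 160.1 and 1297 ± 450.1 CPM (adjusted p = 0.769). On the log2 scale slc38a2 was at 2.77, slc22a7b.3 at 1.55, slc16a1 at 1.36 (ENSDARG00000016963) and 0.99 (ENSDARG00000068572), and slc35d2 at 0.96. The other lists gave 0.970 for glycolysis (ldhb at -1.0, eno3 at -0.79), 0.333 for fatty acid oxidation (echs1 at -2.32, acaa2 at -1.87) and 0.236 for the cell cycle (mki67 at -1.60). They gave 0.709 for motile cilia (cfap210 at 0.75), 0.970 for endocytosis (ehd1 at -1.98) and 0.864 for nephron transcription factors (ppargc1a at -0.33). The reporter gene cdh17 stood at 5999 and 2980.3 CPM (-1.01 ± 0.62, adjusted p = 0.835). The calls ended with RLE scaling, which left 0 genes with 70 up and 14 down at unadjusted p under 0.05, against 6 by DESeq2. They also ended with ComBat before the clustering (n = 3 and 4, 0 genes, 49 up and 18 down at unadjusted p under 0.05). Broader preparation units and a minimum of 500 transcripts (n = 4 and 2) called 1 gene each. The folds of atf3 and fosl1 lean on ZNC151116 (464065 counts, others 15830 and 18919). All calls ended without ZNC150518_D3, that of mknk2 also without ZNC_Day3. The total was 2 without ZNC181016 (hsp90aa1, fos and mknk2 lost), 14 without ZNC151116 and 87 without ZN_MAX_P2, and fosl1 stayed in each.

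Whether proximal-like and distal-like cells differed in their change from day 2 to day 3 was tested within preparations (n = 3 and 2), and no gene of 1270 passed in limma. At unadjusted p under 0.05, 36 genes changed more upward in proximal-like cells and 29 in distal-like cells, and 1 gene was called without ZNC151116. The sodium-proton exchanger slc9a3.1 had the smallest p of the carriers, with a difference of -2.63 ± 0.66 (limma adjusted p = 0.504), followed by slc6a9 at -2.67 (0.740) and slc4a2 at -2.18 (0.855). The difference in stress genes in distal-like cells is therefore not shown to differ from that in proximal-like cells, and cdh17 differed by 0.30.

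Over all kept cells the ages differed in blood and pigment genes. From day 1 to day 2 embryonic globins fell, as hbbe3 (ENSDARG00000038147) from 3240.1 ± 2916 to 3.28 ± 4.14 CPM (log2 -9.63 ± 1.5, n = 3 and 6, adjusted p = 0.00274). So did the melanocyte regulator mitf (ENSDARG00000003732) from 231 ± 125.1 to 2.61 CPM (-6.72 ± 0.82, adjusted p = 0.000407). Both genes were chosen after their values were seen. The erythroid marker list was lower in 9 of 9 genes (camera adjusted p = 2.68e-25) and the pigment and neural crest list in 10 of 10 (1.00e-25), and both held with an estimated correlation (adjusted p = 0.00184 and 0.000879). Hepatocyte markers were higher in 3 of 4 (0.000277, 0.0304 with an estimated correlation). Neural markers were lower (0.000223; adjusted p = 0.227 with an estimated correlation), and markers of epidermis, skeletal muscle, intestine, proximal tubule and exocrine pancreas higher (6.96e-06 to 0.0219; adjusted p between 0.196 and 0.227 with an estimated correlation). Markers of 7 other classes, podocyte and distal tubule among them, did not pass (0.121 to 0.796). The gene lists moved with this cell mix in the same sums: oxidative phosphorylation was higher in 79 of 79 genes (median 1.09, adjusted p = 4.45e-11) and fatty acid oxidation in 22 of 23 (1.32, 2.95e-08), both with adjusted p = 0.614 with an estimated correlation. The whole solute carrier family had a median of 0.42 (0.0164), and the cell cycle was lower in 18 of 21 (-0.65, 7.18e-05). With an estimated correlation the adjusted p was 0.635 for the carriers and 0.614 for the cell cycle. In all 5 genes were called up and 45 down, and 2 up and 20 down without ZNC_Day1_cdh17 and ZNC_D3_080518, a choice made after the data had been seen. DESeq2 called 105 and 88. With matched cells only 7 were called up and 23 down, mitf among them and hbbe3 not (0.0610). The total was 20 without ZNC_D1CTRL, 29 without ZNC_Day1_cdh17 and 128 without ZNC_Day1.

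At day 3 against day 1 all kept cells again had fewer blood and pigment transcripts. Among 2 genes called up and 32 down, mitf fell to a log2 fold change of -5.70 (adjusted p = 0.00220) and the globin hbae1.1 to -6.82 (0.00856). So did the carrier slc2a11b, from 232 to 16.3 CPM (-3.55 ± 0.70, adjusted p = 0.0232), all chosen after their values were seen. Erythroid (1.33e-19) and pigment (1.49e-21) marker lists held with an estimated correlation (adjusted p = 0.00546 and 0.00200). Of the gene lists organic ion carriers were higher in 13 of 13 (0.000589; adjusted p = 0.476 with an estimated correlation) and the cell cycle lower in 21 of 21 (0.00173; 0.911). Within the ZNC_Day titles, with the title series as a block (n = 2 and 2), 21 genes were called up and 20 down. There mitf (-5.09) and hbae1.1 (-6.37) were called, and the slc2a11b call ended (-2.54, adjusted p = 0.270). It also ended without 5 of the 9 preparations. With matched cells only (n = 4 and 3) 0 of 10486 genes were called, with 463 up and 382 down at unadjusted p under 0.05, mitf at -6.23 (adjusted p = 0.0951) and hbae1.1 at -7.11 (0.138). Without ZNC_Day1_cdh17 and ZNC_D3_080518 1 was called up and 9 down. The total was 10 without ZNC150518_D3, 8 without ZNI130317_D3, 22 without both ZNI titles, 17 without ZNC_D1CTRL or ZNC_Day1_cdh17, 18 without ZNC_Day3, 19 without ZNC_Day3_cdh17, 21 without ZNC_D3_080518, 52 without CDH17_D3 and 93 without ZNC_Day1. DESeq2 called 27 and 69 (28.1% up against 5.88%).

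Day 3 against day 2 gave 1 called gene in all kept cells, ENSDARG00000003041, higher by 3.30 on the log2 scale (adjusted p = 0.0461) and called in the fits without ZNC_D3_080518 or ZNC_Day3_cdh17 only, with 0 genes called without each other preparation. Its call also ended with broader preparation units and with matched cells only (up to 0.314). Oxidative phosphorylation was lower in 79 of 79 genes (median -1.04, camera adjusted p = 6.99e-20), the tricarboxylic acid cycle in 21 of 21 (2.81e-09) and ribosomal proteins in 77 of 82 (1.50e-09), each with adjusted p = 0.988 with an estimated correlation. Skeletal muscle (0.0107) and epidermal (0.0491) markers were lower too, and podocyte markers higher in 9 of 10 (0.00965). These had adjusted p = 0.558 with an estimated correlation. The median of all genes was -0.11 in this contrast and -0.20 with RLE or DESeq2 scaling, and moved less in the others.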

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

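The tests of other splits of the preparations, of cell depth and class shares in ZNC_Day1_cdh17, of slc2a1 without each day 1 preparation and of the stress genes in proximal-like cells were chosen only after the results were seen. All others were written beforehand.

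The preparation ZNC_Day1_cdh17 held 2 cells of the pronephric classes among 346 kept cells, although its title names the reporter gene. Shallow cells might have hidden the tubule, but its median of 4414 transcripts per kept cell, against 2262 in ZNC_Day1, argues against that. Tubule cells that the clustering failed to name might be present, but cdh17 transcripts appeared after thinning in 0.867% of its cells (Wilson interval 0.295 to 2.52%), against 29.2% in ZNC_Day1 (23.0 to 36.3%), which argues against that too. Libraries of another age cannot be told apart from day 1 libraries by hmga2, at 533 CPM below the highest value at days 2 and 3 (1340.5) and the other day 1 preparations (1292 and 2210), since it is summed over another mix of cells. Class shares are mixed: erythroid cells made up 6.36% (4.24 to 9.44%) and pigment and neural crest cells 8.38% (5.90 to 11.8%), against 0 and at most 1.35% in every preparation of days 2 and 3; but an unnamed cluster led by neural crest genes held 21.4% (17.4 to 26.0%) of its cells and 40.5% (30.1 to 51.9%) of CDH17_D3 at day 3, and these shares also depend on the sort, which remains open, untested.

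In proximal-like cells slc2a1 fell 78.4-fold from day 1 to day 3. A shift between the 2 proximal-like clusters might do this, but within the largest cluster the log2 fold change was -6.02 ± 0.91 (edgeR adjusted p = 0.00212), which argues against it. RNA from other cells might add slc2a1 at day 1, but the level outside the pronephric classes was 1.00% and 0.553% of the proximal-like level in the day 1 preparations. A single day 1 preparation might carry the change, but the log2 fold change nearest 0 without either was -5.50 ± 1.1 (edgeR adjusted p = 0.107, the highest of the refits without 1 preparation). A difference in age stays open, untested, as does any other difference between preparations of days 1 and 3.

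In distal-like cells the immediate-early and heat-shock genes were higher at day 3 than at day 2, with a ratio of summed levels of 2.69 (n = 2 and 3). Handling of the day 3 preparations might induce them in every cell type: outside the pronephric classes the ratio was 1.88 in the same preparations (1.38 without ZN_MAX_P2 and 3.42 without ZNC151116, which has 12 such cells), so handling and a response to age cannot be told apart. A change limited to distal-like cells might be the alternative, but proximal-like cells of the same preparations gave 2.33, which argues against it. Levels in preparations outside this comparison did not follow age: proximal-like cells of ZNI160317_P1 at day 2 stood at 12070 CPM (day 3 4847 to 10558), and all kept cells of ZNC160317_P1 and ZNI160317_P1 at 18889 and 14402, against at most 8303 at day 3, but both titles share a date and the cells of ZNI160317_P1 are called "Split", so they may be 1 batch. A biological difference in age shared by the cell types stays open, untested. So does a link to mitochondrial RNA, at 45.8 and 43.5% in the day 3 preparations compared and 27.4 to 38.5% at day 2.

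Single preparations stood apart from the rest of their age in 8 of 56 groups examined, where chance gives about 1 in 20. Distal-like cells made up 69.4% of ZNC151116 (63.0 to 75.1%) against 2.06 to 16.9% in the other day 2 preparations. Multiciliated-like cells made up 7.69% of ZNC181016 (3.33 to 16.8%) against 0 to 1.80%. In the pronephric classes at day 2, neff2 stood at 111 CPM in ZNI160317_P1 (0 to 37.4 elsewhere), rn7sk at 54.0 in ZN_MAX_P1 (0 to 13.9) and slc2a1 at 3847 in ZNC181016 (225 to 1148). In proximal-like cells slc2a1 stood at 5454 in ZNC181016 (826 to 1773 in the other day 2 preparations), slc3a1 at 482 in ZN_MAX_P2 (112.5 to 193) and mafb at 670.1 in ZNC_Day3 (369 to 415 in the other day 3 preparations). Outside the comparisons, 5.14% of the transcripts of ZNC_Day3_cdh17 lay in wells of the unused part of the plate, against 0.303 to 4.68% in the other preparations.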

How the results depend on the processing

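Every alternative was fixed beforehand except leaving out ZNC_Day1_cdh17 and ZNC_D3_080518 together, added after the data had been seen. Over all settings but the leaving out of single preparations, 4615 results were recomputed: 3824 kept direction and side of the threshold, 544 became weaker, 151 stronger, 77 moved and 19 reversed. The cause of these changes was not tested.

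With no filter on low counts, the called genes numbered 149, 4 and 90 in all kept cells (day 2 against day 1, day 3 against day 2 and day 3 against day 1, in this order throughout), 28, 47 and 32 in the pronephric classes, 54 and 58 in the first 2 contrasts of proximal-like cells and 3 in distal-like cells. Pronephric wt1b turned to -0.000592 at day 3 against day 1. DESeq2 called 193, 23 and 96 genes in all kept cells, 61, 18 and 50 in the pronephric classes and 79, 39 and 1.1e+02 (57 up and 55 down) in proximal-like cells. RLE scaling called 30 at day 2 against day 1 in proximal-like cells and 0 in distal-like cells.

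Without the preparations titled ZNI, all kept cells gave 0 genes at day 3 against day 2 and 22 at day 3 against day 1, the pronephric classes 3, 0 and 6, proximal-like cells 36, 18 and 23, and the pronephric lists 7 at day 2 against day 1 and 0 at day 3 against day 1. Without the preparations whose titles name cdh17, all kept cells gave 33, 0 and 16, the pronephric classes 4 at day 3 against day 1 and proximal-like cells 5 and 30 in the last 2 contrasts; wt1b in all kept cells turned to 0.20 at day 3 against day 2, and pronephric pax2 to -0.52 at day 3 against day 1. Without ZNC_Day1_cdh17 and ZNC_D3_080518, all kept cells gave 22 at day 2 against day 1 and 10 at day 3 against day 1.

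With each library as a replicate, which treats libraries of the same preparation as independent, counts were 896, 476 and 459 in all kept cells, 422, 573 and 1.9e+02 (124 up and 61 down) in the pronephric classes and 235, 103 and 29 in proximal-like cells. Pronephric wt1b turned to -1.71 at day 2 against day 1 and to 2.23 at day 3 against day 2 (edgeR adjusted p = 0.0363), pax2 to -0.78 at day 3 against day 1, and in proximal-like cells at day 3 against day 2 g6pc1 to -0.0313 and cfap45 to 0.17. Within the ZNC_Day titles, a block for the series left 14 of 34 results as they were and weakened 19, and turned cdh17 in all kept cells to 1.40 at day 3 against day 1.

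With matched cells only, the counts were 30 at day 2 against day 1 and 0 at day 3 against day 1 in all kept cells, and 75 and 124 in the pronephric classes and 96 and 1 in proximal-like cells for the first 2 contrasts. Broader preparation units gave 0 and 64 in the last 2 contrasts of all kept cells, 0 and 6 in those of the pronephric classes and 1 in distal-like cells. With all variable genes kept in the clustering, the pronephric classes gave 3 at day 2 against day 1 and 2 at day 3 against day 1; slc2a2 turned to 0.0836 and fbp1b to 1.36 at day 2 against day 1, and fbp1b to 1.26, tpi1 to 0.13 and wt1b to -0.56 at day 3 against day 1.

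A minimum of 2000 transcripts per cell gave 0 genes in the pronephric classes and 5 in proximal-like cells at day 3 against day 2, 2 lists at day 2 against day 1, and a difference of 0.464 in the pronephric share at day 3 against day 2. A minimum of 500 gave 27 and 16 in the first 2 contrasts of proximal-like cells, 1 in distal-like cells, and pronephric wt1b at -0.0311 at day 3 against day 1. After ComBat, proximal-like cells gave 34 at day 2 against day 1 and 86 at day 3 against day 1 and distal-like cells 0, where cfap45 turned to 0.0407. A prior weight of 0.5 in the segment test turned dnah9l to -0.0194.

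For the lists, an estimated correlation left 0, 0 and 0 passing, and fry likewise 0, 0 and 0. In all kept cells 10 passed at day 2 against day 1 and 10 at day 3 against day 1, and motile cilia turned upward at day 2 against day 1 (camera adjusted p = 0.490).

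Leaving out each preparation in turn gave 3399 results, of which 2630 stayed, 650 became weaker, 19 stronger, 70 moved and 30 reversed. Where day 1 kept 1 preparation, the lone sample was assumed to vary like the other groups. Called genes ranged from 20 to 128, 0 to 1 and 8 to 93 in all kept cells, from 2 to 6, 0 to 8 and 2 to 8 in the pronephric classes, from 4 to 38, 3 to 16 and 6 to 30 in proximal-like cells, from 0 to 87 in distal-like cells and from 0 to 1 in the segment test, and passing lists from 1 to 10, 5 to 8 and 0 to 10. The difference in the pronephric share at day 3 against day 1, 5.42, ranged from -4.59 to 15.9. Those in transcripts per cell were -277 at day 2 against day 1 (-761 to 504) and -705 at day 3 against day 1 (-1189 to 75.7), in genes per cell -145 (-344 to 141) and -256 (-455 to 29.6), and in genes after thinning 2.83 at day 3 against day 1 (-1.67 to 10).

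Log2 fold changes that crossed 0 were, in all kept cells, wt1b at day 3 against day 2 (-0.87 to 0.62) and cdh17 at day 3 against day 1 (-0.85 to 0.38). In the pronephric classes they were pax8 (-0.0373 to 0.83) and wt1b (-0.48 to 7.69) at day 2 against day 1, pck1 (-0.39 to 0.47) and wt1b (-1.74 to 0.55) at day 3 against day 2, and wt1b at day 3 against day 1 (-0.85 to 6.87). Proximal cdh17 ranged from -0.10 to 0.23 at day 2 against day 1 and distal cfap45 from -1.13 to 0.0379. In the segment test hmgb2b ranged from -0.39 to 3.63, pcna from -0.42 to 2.20, dnah9l from -0.52 to 0.68, ehd1 from -0.0780 to 3.46 and irx3 from -2.90 to 0.00447.

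Not run were the series block for the pronephric classes, where ZNC_Day1_cdh17 has 2 cells, the distal and segment contrasts with day 1, libraries as replicates, the 2000 minimum and matched cells for distal-like cells, and, for proximal-like cells against day 1, the 2000 minimum, the higher Leiden resolution and all variable genes. The higher resolution was also not run for distal-like cells. Replicate numbers follow the order of accession and pair nothing, so no paired analysis was run beyond the series block.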

Other observations

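The tests of other splits were chosen only after the results were seen. That of cdh17 was written beforehand.

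Several unnamed clusters had distinct genes. Steroid synthesis genes (star, cyp11a1, cyp11c1 and nr5a1), known from the interrenal gland, led a cluster of 0 cells at day 1, 38 at day 2 and 10 at day 3. The mesenchymal transcription factor genes hand2 and nkx2-3 led another, with 0, 62 and 49 cells. The neural crest genes sox10 and ednrab led a cluster of 87, 6 and 34 cells. The hormone gene stc1, with the kidney cadherin gene cdh16, led a cluster of 1, 11 and 41 cells, mostly from ZNC_Day3_cdh17. None of these clusters met the naming rule for a marker list, and they entered only the comparisons of all kept cells.

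In ZNC_Day3_cdh17, 138 of 242 kept cells were intestine-like. Whether intestinal cells transcribe cdh17 was not decided. After thinning cdh17 appeared in 23.9% of these 138 cells (Wilson interval 17.6 to 31.7%), against 13.7% (7.61 to 23.4%) outside the pronephric and intestine-like classes. With the stc1 cluster in the latter, this missed the preset excess of over 3 times. It was passed in ZNI130317_D3 (6 of 13, 23.2 to 70.9%, against 10.1%, 6.57 to 15.2%) and not in ZNC_Day3 (0 of 8). Gut taken with the kidney, in cells passing the sort without the reporter, also stays open, untested. Staining of sections for the reporter at day 3 would test this.

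Other ways of splitting the same preparations show how often chance gives as many calls. In all kept cells, 3 of 84 splits for day 2 against day 1, the real one included, called at least the 50 genes of the real split, and the highest other called 698, with ZN_MAX_P1, ZN_MAX_P2 and ZNC_Day1 set apart, which points to a structure of the preparations. For day 3 against day 1, 2 of 84 called at least 34 genes (highest other 62). For day 3 against day 2, 10 of 100 splits drawn from 462 called at least 1 gene (highest other 150). In the pronephric classes at day 3 against day 2, 13 of 100 called at least 1 gene (highest other 139) and 54 of 100 at least 5 lists (highest other 12). In proximal-like cells at day 3 against day 2, 2 of 100 called at least 9 genes (highest other 13). If the preparations are exchangeable, chance is less likely for all kept cells against day 1 and proximal-like cells than for the other 3 results. Chance is not excluded, as the shares are unadjusted. Titles that share a date or stem make exchange doubtful, so these shares of splits may be too small. No splits were run for pronephric and proximal-like cells against day 1 or for distal-like cells, with fewer than 3 preparations at an age.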
